A study of Mus musculus with 24 samples.

How the data were processed

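RNA was measured in 24 libraries of mouse leukaemia cells taken from bone marrow, in 8 groups of 3 libraries. Per the labels' protocols, total RNA was extracted with TRIzol, polyadenylated RNA was selected on magnetic beads, and directional libraries were made with a kit that keeps the strand of origin. Per the submitters' processing notes, reads were aligned with STAR to the mouse genome build mm10. The read counter, the gene annotation, the strand setting and the software versions are not given in the sources used here. The deposited values are whole-number read counts per gene symbol, with 1 column for each library. The file held 24046 genes, of which 2194 had no read in any library. Because the strand setting is not given, genes that overlap a neighbour, and microRNA or small nucleolar RNA entries inside a host gene, are uncertain, as are near-identical copies such as Hba-a1 and Hba-a2.

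Each library was placed in a group by its title. The titles and the cell type descriptions of the VavCre libraries name the same gene. Those of both MxCre sets name different genes: the set titled A2 has Arid1b in its cell type description, and the set titled A1b has Arid2. These sets are therefore named by their titles, and the deleted gene is taken from neither label. Apart from punctuation, column names in the count table matched the titles for all 24 libraries, and 0 columns were left unused. The tests, gene lists, rule for naming genes and most of the alternatives were chosen before the data were examined.

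Counts were analysed with edgeR version 4.0.16 in R 4.3.3. Genes were kept by filterByExpr with the 8 groups and its default minimum count of 10 and total of 15, which left 14099 genes. Library sizes were scaled by the trimmed mean of M values. A quasi-likelihood model with robust estimation was fitted to all 24 libraries with a mean for each of the 8 groups, so that the groups shared 1 estimate of the spread with 16 residual degrees of freedom. The common biological coefficient of variation was 0.4. Each contrast compared the 3 floxed with the 3 control libraries of its own set, no controls being shared between sets. All 6 pairs of sets were compared by the difference of their contrasts, and the controls of both sets with the same Cre were compared directly. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 within each contrast. Adjusted p-values are from this edgeR quasi-likelihood test unless another test is named. Levels are CPM (counts scaled to a common library size with the scaling factors above), given as mean ± SD over 3 libraries, and log2 fold changes are floxed over control with their standard error (SE).

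Genes were named by a fixed rule. Arid1b and Arid2 were reported in every library. For each set, the 8 highest and 8 lowest log2 fold changes were taken among called genes whose floxed libraries all lay on 1 side of every control library, with a mean of at least 2 CPM, leaving out predicted genes, pseudogenes and antigen receptor segments. Up to 4 called members of each gene list were added, or up to 2 members with the smallest p where none was called, and the 5 genes with the smallest p of each difference between sets. Where a group held 3 counts or fewer in total, the ratio of summed counts is given with its 95% counting interval, or, at 0 counts, as a lower bound from a floor of 3 counts over the group. Such intervals and floors cover counting error only.

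The gene lists were the SWI/SNF core, BAF-specific, and PBAF and ncBAF subunits; MLL-fusion targets and self-renewal genes; stem and progenitor genes; genes of granulocytic maturation, of monocytes and macrophages, of MHC class II and dendritic cells, and of erythroid, B, T and NK, megakaryocyte, mast cell, basophil and eosinophil, and stromal and endothelial cells; and genes of the interferon response, NF-kB and inflammation, immediate-early genes, the cell cycle, p53 targets, MYC and ribosome biogenesis, glycolysis and hypoxia, nuclear oxidative phosphorylation genes, cholesterol and fatty acid synthesis, the unfolded protein and amino acid stress response, heat shock, sex-linked genes, cell adhesion and homing, and apoptosis regulators. A further list, of mitochondrially encoded genes, had 0 of its 13 members in the count table and was not analysed here. Lists were tested with camera in limma 3.58.1 on voom log2 CPM at a preset correlation of 0.01, repeated with an estimated correlation and with fry, with Benjamini-Hochberg adjustment over the lists of each contrast. Gene positions are from the RefSeq annotation of GRCm38, the build also called mm10, and were found for 99.5% of the tested genes. Exon lengths and the positions of Arid1b and Arid2 are from GENCODE M21 on the same build, with a length for 95.3%.

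Totals ran from 12069153 to 38315410 counts per library. The VavCre Arid2 set was the deepest, at 28079167 to 38315410 counts, and the MxCre set titled A1b the shallowest, at 12069153 to 17231014. Replicates differed by far more than sampling noise: the closest pair of libraries in a group had a chi-square of 14.4 per gene, so no library was counted as a copy of another. The fit was tested on counts simulated from the real means, library sizes and dispersions, in which 48 to 50 of the tested genes of a set were changed at each of 4 sizes. In the VavCre Arid1b simulation, over 13820 genes, 34.7% of genes changed 2-fold, 57.1% changed 4-fold and 82.0% changed 8-fold were called, and 1.53% of calls were false. In the VavCre Arid2 simulation, over 13849 genes, these shares were 32.7%, 55.1% and 89.8%, with 4.38% false. For the MxCre set titled A2, over 13831 genes, they were 32.7%, 55.1% and 80.0%, with 3.76% false. For that titled A1b, over 13854 genes, they were 33.3%, 76.0% and 85.7%, with 9.03% false. The simulated counts came from means, library sizes and dispersions alone, and so lack differences shared by many genes, such as those with sex. The shares describe such counts only, and the error of the real calls was not measured.

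Alternatives tried were DESeq2 size factors within edgeR, no filter on low counts, a filter of 1 CPM in 3 libraries, estimation without the robust option, the replicate number as a block, a fit to the 6 libraries of a set alone, DESeq2 version 1.42.0, voom with sample weights, a fold change limit, and leaving out each library in turn. After the data had been seen, a term for Y-positive libraries (Kdm5d above 10 CPM), a fit without 3 libraries that stood apart, a correction for gene length, and tests without genes of chromosomes X and Y or of chromosome 12 were added. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.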

Results

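Leukaemia cells driven by the MLL-AF9 fusion were collected from the bone marrow of moribund mice that had received transplanted cells, and their RNA was measured in 4 sets. Arid1b and Arid2 encode DNA-binding subunits of the SWI/SNF chromatin remodelling complexes, Arid1b in the BAF form and Arid2 in the PBAF form. Each set has 3 libraries with Cre and unfloxed alleles (control) and 3 with Cre and floxed alleles (floxed). In the VavCre Arid1b set and the VavCre Arid2 set, Cre is active in blood cells from early development. In the MxCre sets, Cre is induced by pIpC, an interferon-inducing RNA, given at 12.5 µg per g body weight in 3 injections from day 21 after transplantation. The titles and cell type descriptions of both MxCre sets name different genes: the MxCre set titled A2 is described as Arid1b cells, and the MxCre set titled A1b as Arid2 cells. They are named here by title only, and which gene was deleted in them is left open. The labels do not say whether the libraries of a group come from separate primary leukaemias, so the p-values measure only the spread between these samples. Adjusted p-values are Benjamini-Hochberg values of edgeR's quasi-likelihood test over 14099 genes, and counting intervals cover counting error only.

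Reads from Arid1b and Arid2 were present in all 24 libraries, and neither gene passed the threshold in any set. Arid1b (chromosome 17, 4994332 to 5347656, GRCm38) was at 257 ± 96.3 CPM (mean ± SD, n = 3) in the controls of the VavCre Arid1b set and at 164 ± 22.8 in the floxed libraries, a log2 fold change of -0.65 with a 95% interval of -1.60 to 0.30 (edgeR adjusted p 0.407). Arid2 (chromosome 15, 96287518 to 96404992) was at 299 ± 125 CPM in the controls of the VavCre Arid2 set and at 256 ± 51.6 in the floxed libraries, a log2 fold change of -0.22 with an interval of -1.09 to 0.64 (edgeR adjusted p 0.802). The other ARID gene lay lower by a similar or larger amount, with log2 fold changes of -0.62 for Arid2 in the VavCre Arid1b set (edgeR adjusted p 0.381) and -0.58 for Arid1b in the VavCre Arid2 set (0.507). In the MxCre set titled A2, Arid1b went from 265 ± 158 to 178 ± 7.68 CPM (edgeR adjusted p 0.703) and Arid2 from 345 ± 183 to 289 ± 53.4 (0.880). In the MxCre set titled A1b, Arid1b went from 174 ± 18.9 to 190 ± 117 CPM (edgeR adjusted p 0.906) and Arid2 from 229 ± 50.2 to 309 ± 163 (0.611). Single libraries ranged for Arid1b from 55.7 CPM (floxed 2 of the MxCre set titled A1b) to 442 (control 3 of the MxCre set titled A2), and for Arid2 from 121 to 547 in the same libraries. In that floxed library longer genes lay lower in general, with a Spearman correlation across genes of -0.56. The deleted exons are not given in the labels, and a transcript without them still gives reads, so these counts test neither the deletion nor its extent.

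**Figure D1:**
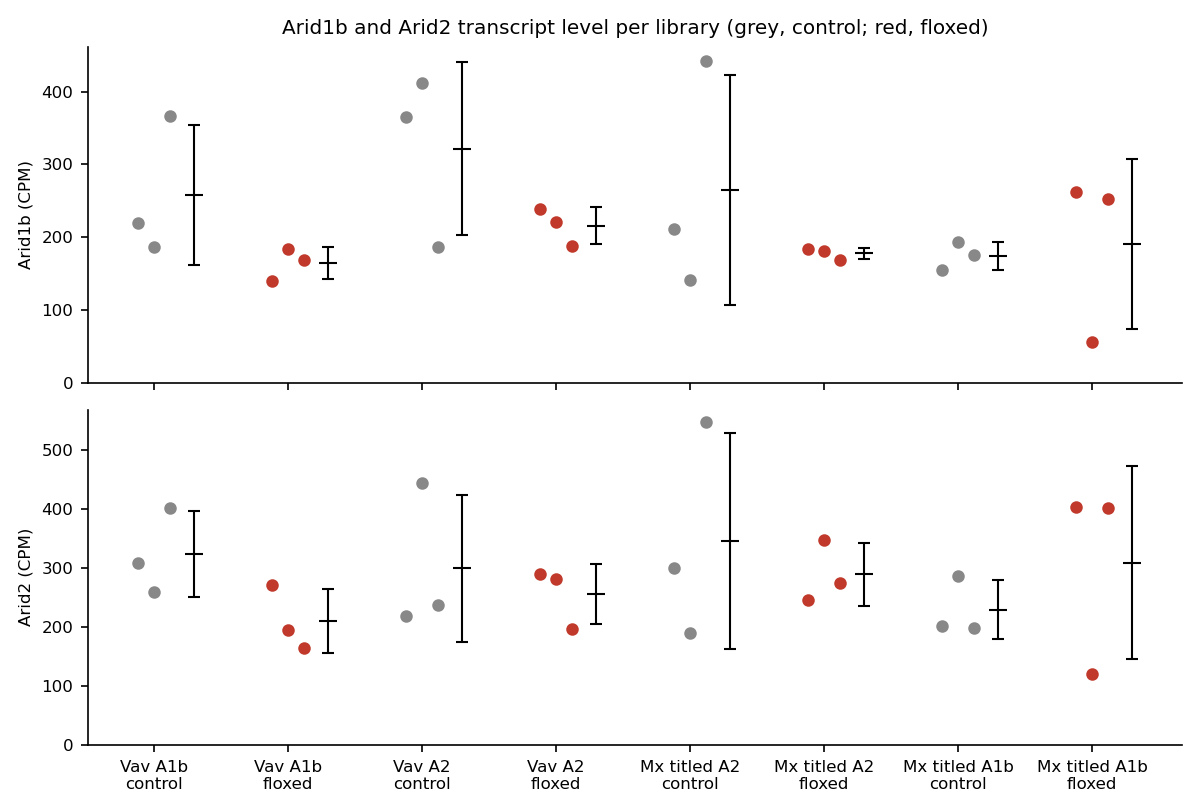
Level of Arid1b and Arid2 in CPM in each of the 24 libraries, by set and group (grey, control; red, floxed), with bars for the group mean ± SD. Except for Arid1b in the VavCre Arid1b set, floxed and control libraries overlap, and neither gene passed the threshold in any set.

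Libraries of a group differed from each other by much of what separated the groups. The first principal component of log2 CPM held 30.7% of the variance and the second 11.9%. Along the first, the floxed libraries of the VavCre Arid1b set lay at 66.4 to 81.0 against -81.9 to 22.1 for their controls, and those of the VavCre Arid2 set at 19.6 to 54.0 against -74.2 to -36.7. In the MxCre sets floxed and control libraries overlapped on it. Xist, transcribed from the inactive X chromosome of female cells, and Kdm5d, on the Y chromosome, split the libraries by sex: 10 had Kdm5d above 10 CPM. All 3 controls of the VavCre Arid1b set were Y-positive and all 3 floxed libraries Y-negative, with Xist at 26.6 ± 34.7 against 2980 ± 175 CPM. In the MxCre set titled A2 this was turned around, with Y-negative controls and Y-positive floxed libraries, and in the remaining sets it was mixed. Sex and genotype are therefore confounded within those 2 sets. Genes on chromosome 12 lay higher in control 3 of the VavCre Arid1b set, by a median of 0.51 on the log2 scale over 381 genes, while its other autosomes lay between -0.06 and 0.07.

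**Figure D2:**
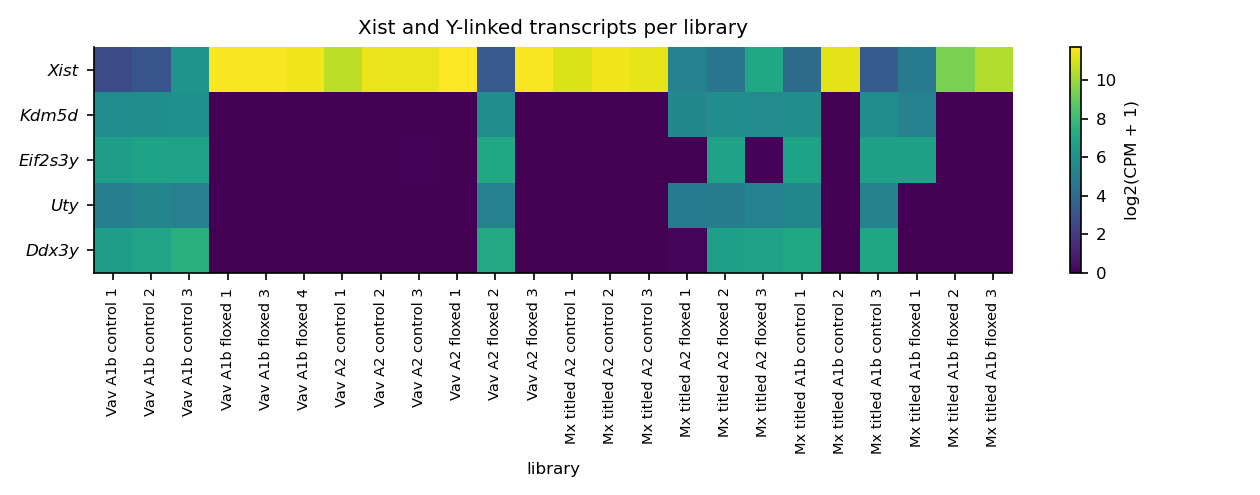
Level of Xist and of 4 Y-linked genes in each library, coloured by log2 of CPM plus 1. The 10 libraries with Kdm5d above 10 CPM include all 3 controls of the VavCre Arid1b set and all 3 floxed libraries of the MxCre set titled A2.

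**Figure D3:**
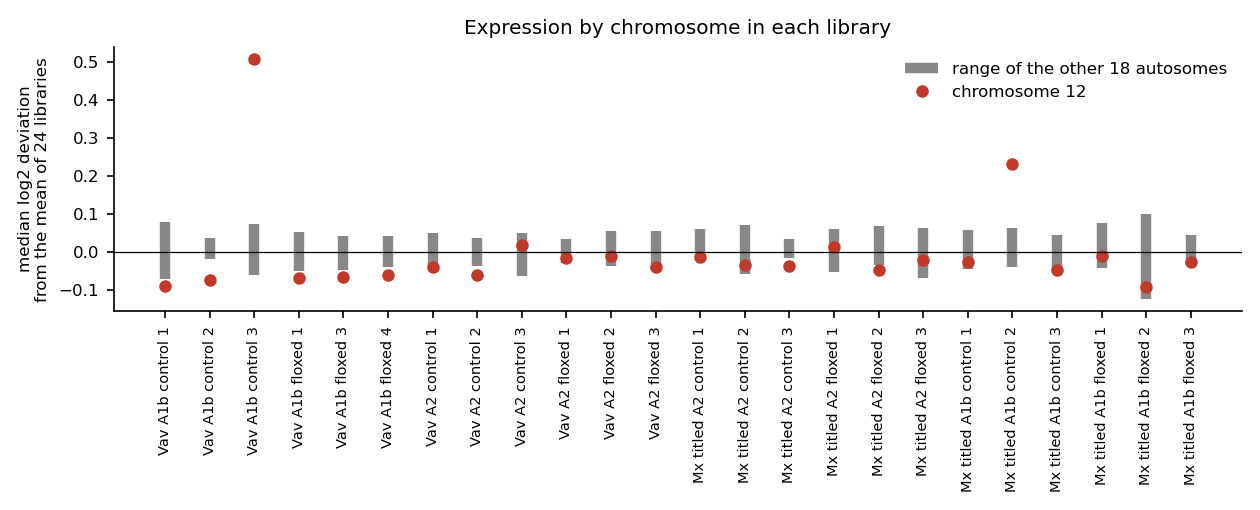
Median log2 deviation of genes on chromosome 12 in each library from the mean of all libraries (red), with the range of the other 18 autosomes (grey). Control 3 of the VavCre Arid1b set lies at 0.51 and control 2 of the MxCre set titled A1b at 0.23, against at most 0.02 in the other libraries.

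A few libraries held much more of some transcripts than the rest of their set, in genes singled out after their values were seen. Hba-a1, an alpha-globin gene of red cells whose copies share reads, was at 72.7 CPM in floxed 3 of the MxCre set titled A2 and at most 0.868 in that set's other libraries. The 10 most abundant genes took 16.6% of the counts of that library, against 3.03% to 4.77% in the other libraries, and Ltf, a granule protein of maturing neutrophils, reached 1483 CPM. Floxed 2 of the MxCre set titled A1b had Hba-a1 at 58.2 CPM and S100a8, an abundant neutrophil transcript, at 4489 CPM, and its genes were lower the longer they were, with a Spearman correlation across genes of -0.56. Immediate-early genes, which respond within minutes to handling or signals, had a mean log2 CPM of 7.32 in floxed 3 of the MxCre set titled A1b and of 2.91 to 4.15 in the set's other 5 libraries.

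In the VavCre Arid1b set, genes called higher in floxed leukaemias included some of antigen presentation and of monocytes and dendritic cells, though neither list of these genes held with an estimated correlation. Cd74, the invariant chain that loads MHC class II, rose from 9.37 ± 6.24 to 749 ± 581 CPM, a log2 fold change of 6.32 ± 1.42 (SE; edgeR adjusted p 0.0166). Ccr2, the receptor that brings monocytes out of the marrow, rose from 41.6 ± 12.6 to 667 ± 385 CPM (edgeR adjusted p 0.0149), and Itgax, which encodes the dendritic cell integrin CD11c, rose by 3.39 ± 0.78 on the log2 scale (0.0179). Ikzf2, which encodes the transcription factor Helios, fell from 283 ± 117 to 2.69 ± 0.967 CPM (edgeR adjusted p 0.0280). Kit, the stem cell factor receptor of progenitors, fell from 137 ± 53.6 to 35.7 ± 16.7 CPM (edgeR adjusted p 0.0274), and so did the granulocyte regulators Cebpe (log2 fold change -1.89, 0.0261) and Gfi1 (-2.27, 0.0443), while Cebpa, a regulator of myeloid progenitors, rose (1.01, 0.0175). The lists of granulocytic maturation and of stem and progenitor genes did not pass in this set (camera adjusted p 0.449 and 0.225), so these are single genes. In all, 926 of 14099 genes changed, 496 higher and 430 lower, and 703 of them by more than 2-fold. The 3 floxed libraries all lay to 1 side of the 3 controls for 4568 genes, or 32.4%. The mean over the 10 splits of these libraries is 10%, which a single split can exceed by chance, as genes vary together. The number of genes was 65 (17 higher and 48 lower) without control 1 and 403 (170 and 233) without control 3. It was 62 (32 and 30) without floxed 3 and 305 (156 and 149) without floxed 4. Fits with fewer libraries have less data, so these drops do not show that the calls rest on these libraries. The balance of directions depends on the fit. With a term for Y-positive libraries, chosen after the data were seen, 101 genes (32 and 69) were called, 82 of them among the 926. A fit to the set's 6 libraries alone called 1061 (698 and 363), DESeq2 1815 (1013 and 802) and voom with sample weights 4189 (2096 and 2093).

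Many of the largest changes in the VavCre Arid1b set were in genes near 0 in 1 of the groups. Among those that rose were Cd40, a costimulatory receptor of antigen-presenting cells, from 0.0920 to 13.1 CPM (edgeR adjusted p 0.0366), Apbb1, an adaptor of the amyloid precursor protein, from 0.333 to 36.2 (0.00765), Dmrtb1, a regulator of germ cells, from 3.51 ± 4.49 to 288 ± 9.47 (0.0179), and Dgki, a diacylglycerol kinase, by 6.35 ± 1.53 on the log2 scale (0.0211). Over the alternatives the log2 fold change of Dmrtb1 ran from 4.86 to 8.29 and that of Dgki from 4.42 to 7.92. Fgf10, a growth factor, Tnip3, an inhibitor of NF-kB, and Klrb1b, an NK cell receptor, had 1 to 3 counts over the controls, and their ratios of summed counts were 395 (95% counting interval 70.6 to 15600), 129 (35.3 to 1070) and 100 (34.0 to 489). Among those that fell, Prg3, an eosinophil granule protein, went from 125 ± 120 to 0.818 ± 0.458 CPM (edgeR adjusted p 0.00909), Aldh1l1, an enzyme of folate metabolism, from 14.6 ± 15.2 to 0.178 ± 0.128 (0.00806), and Scn2b, a sodium channel subunit, from 24.7 ± 26.8 to 0.239 ± 0.168 (0.0444). Over the alternatives their log2 fold changes ran from -7.03 to -5.04 for Aldh1l1 and from -7.55 to -5.10 for Scn2b. The call was lost in 3 of 19 and 11 of 19 alternatives. Serpina11, Hormad2, Pik3c2g and Rasgef1a had 1 to 3 counts over the floxed libraries, with ratios of control to floxed of 550 (98.3 to 21800), 362 (99.7 to 2990), 312 (55.5 to 12400) and 93.5 (31.6 to 456). The level of Hormad2 rests on control 1, at 35.5 CPM against 0.114 and 0.304 in the other controls, as does that of Pik3c2g, at 15 CPM against 0.400 and 0.101, and without control 1 neither was called and the log2 fold changes were -2.50 and -3.48. The ratio of Serpina11 was 247 without control 1, and that of Tnip3 76.7 without floxed 3. Serpina11, a protease inhibitor gene, lies on chromosome 12 at 103980243. Over the 49 genes named for this set by rule and 6 single-library omissions, the call held in 103 cases and was lost in 191. No direction changed, but the leading genes were chosen with all floxed libraries to 1 side of the controls. Leaving out 1 library could hardly turn them around, so kept directions are no sign of stability.

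**Figure D4:**
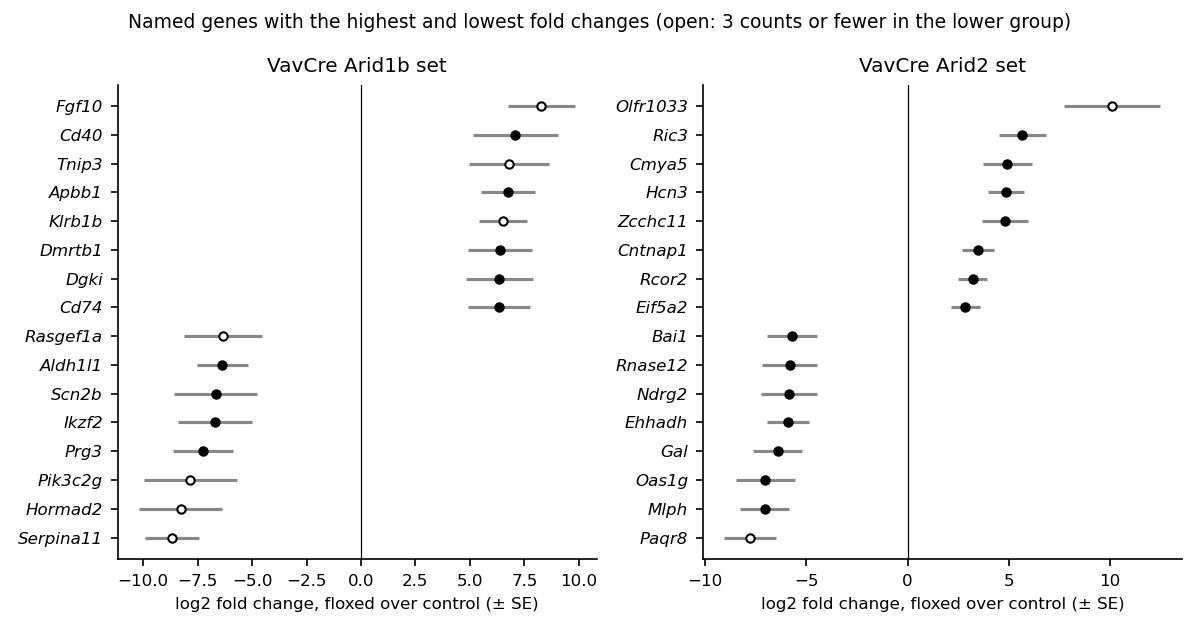
Log2 fold change, floxed over control, of the genes with the largest changes named for the VavCre sets, with SE. Open symbols mark genes with 3 counts or fewer over the lower group, whose fitted values depend on the prior count. Cd74 rose by 6.32 and Ikzf2 fell by 6.70 in the VavCre Arid1b set.

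**Figure D5:**
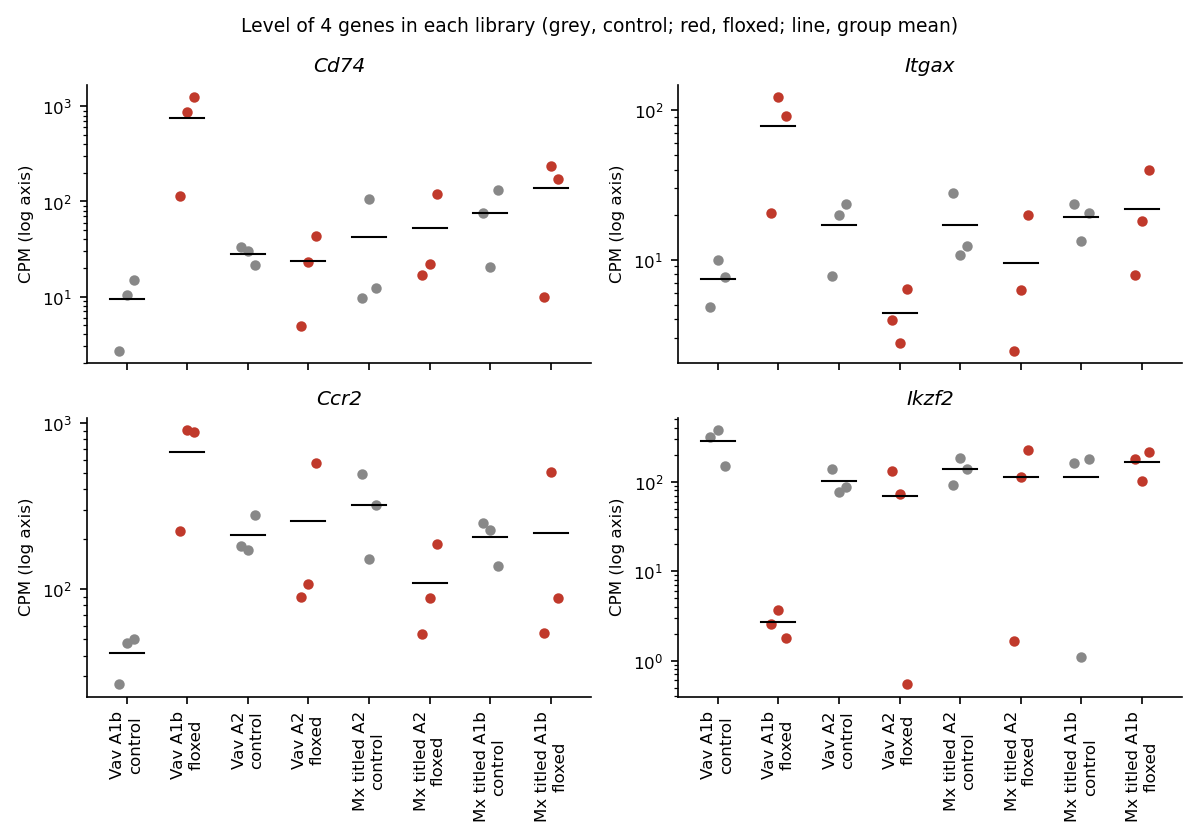
Level of Cd74, Itgax, Ccr2 and Ikzf2 in CPM in each library on a log axis, grey for control and red for floxed, with the group mean as a line. In the VavCre Arid1b set every floxed library lies on 1 side of every control for these 4 genes.

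Among the fixed gene lists in the VavCre Arid1b set, genes of MHC class II and dendritic cells had the smallest camera p. Of 16 tested, 10 rose over all genes and 13 adjusted over the list alone, among them Clec9a, a receptor of cross-presenting dendritic cells, and Batf3, their transcription factor, by 5.32 and 4.30 on the log2 scale (camera adjusted p 2.34e-08 for the list). Monocyte and macrophage genes were higher (4 of 26 rose, and 10 rose and 1 fell adjusted over the list alone; 9.28e-05), including the scavenger receptor Cd163 and the transcription factor Klf4. NF-kB and inflammatory genes were higher (4 of 21, and 12 adjusted over the list alone; 5.5e-05), including Nfkb1 itself and the inflammasome sensor Nlrp3. Immediate-early genes were higher (3 of 18, and 3 adjusted over the list alone; 0.00171), as were adhesion and homing genes (2 of 17 rose, and 7 rose and 1 fell adjusted over the list alone; 0.00494). Cell cycle genes lay lower in 32 of 32, with 0 passing over all genes by edgeR and 0 adjusted over the list alone (6.56e-05). Cholesterol and fatty acid synthesis genes were lower (2 of 24, and 3 adjusted over the list alone; 0.000121), and so were T and NK genes (Gzmb fell and Cd28 rose of 21; 0.00937), a call lost without floxed 1 (0.0758). With an estimated correlation the camera adjusted p was 0.717 for each of these 8 lists, so none held, and none passed by fry.

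In the VavCre Arid2 set, most genes called by edgeR fell, including a gene of neutrophil granules and a gene of the B cell receptor, though the balance depends on the fit. Mmp9, a gelatinase stored in neutrophil granules, fell from 250 ± 181 to 8.13 ± 5.05 CPM, a log2 fold change of -4.94 ± 0.98 (SE; edgeR adjusted p 0.0192). Cd79b, a part of that receptor, fell from 25.0 ± 3.67 to 2.82 ± 2.10 CPM (edgeR adjusted p 0.0478), Fas, a death receptor and p53 target, from 13.9 ± 2.98 to 0.677 ± 0.768 (0.0150), and Bai1, a receptor for dying cells, from 35.3 ± 3.59 to 0.666 ± 0.691 (0.0295). Zcchc11, a terminal uridylyltransferase that modifies microRNAs, rose from 1.51 ± 0.349 to 42.1 ± 14.7 CPM (edgeR adjusted p 0.0467), and Hcn3, an ion channel gene, from 0.318 to 9.34 (0.0150). The leukaemia-sustaining genes Hoxa9, at 329 ± 43.8 against 64.1 ± 38.5 CPM, and Hoxa10, at 133 ± 33.1 against 11.1 ± 9.59, lay lower and did not pass (edgeR adjusted p 0.0534 and 0.0507). Flt3, a receptor of early progenitors, lay higher, at 22.9 against 639 CPM, and did not pass (edgeR adjusted p 0.105). In all, 185 of 14099 genes changed, 35 higher and 150 lower, and 165 of them by more than 2-fold. Floxed and control libraries did not overlap for 5086 genes, or 36.1%. The mean over the 10 splits of these libraries is 10%, which a single split can exceed by chance. The number of genes was 61 without control 1, 27 without control 2, 15 without floxed 1 and 16 without floxed 2, and 104 with a term for Y-positive libraries, 96 of them among the 185. DESeq2 called 1095 genes (373 higher and 722 lower), voom with sample weights 4679 (2171 and 2508), a fit to the set's 6 libraries alone 1030 (432 and 598), and a fit without 3 libraries of other sets (control 3 of the VavCre Arid1b set, floxed 3 of the MxCre set titled A2 and floxed 2 of that titled A1b) 1144 (482 and 662).

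Other genes named for the VavCre Arid2 set were of low level. Ric3, a chaperone of acetylcholine receptors, Cmya5, a muscle protein gene, Cntnap1, an axonal adhesion gene, Rcor2, a corepressor, and Eif5a2, a translation factor, rose by 2.86 to 5.67 on the log2 scale (edgeR adjusted p 0.0213 to 0.0497). Olfr1033, an olfactory receptor gene, had 0 counts in the controls and was at least 211-fold higher in the floxed libraries, taking a floor of 3 counts over the group. It was at 11.3 and 7.46 CPM in floxed 1 and 2 and at 0.0610 in floxed 3, and the bound was 127 without floxed 1. The call was lost without either of floxed 1 and 2 and without any of the controls. Paqr8, a progesterone receptor gene, had 3 counts over the floxed libraries and a ratio of control to floxed of 261 (95% counting interval 89.0 to 1270). Mlph, which links melanosomes to myosin, fell from 17.1 to 0.123 CPM (edgeR adjusted p 0.0111), Oas1g, an interferon-induced gene, from 10.5 to 0.0759 (0.0255), and the neuropeptide gene Gal from 8.24 to 0.0882 (0.0161). Ehhadh, of peroxisomal fat oxidation, Ndrg2, a differentiation gene, and Rnase12 fell by 5.82 to 5.90 on the log2 scale, with edgeR adjusted p of 0.0135 to 0.0454. Rnase12 was at 32.1 CPM in control 2 and at 2.82 and 0.781 in the other controls, and without control 2 it was not called, at a log2 fold change of -3.10. Over the 22 genes named for this set by rule and 6 single-library omissions, the call held in 40 cases and was lost in 92. No direction changed, which the choice of called and separated genes largely set in advance.

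Of the gene lists in the VavCre Arid2 set, that of granulocytic maturation was lower (1 of 27 fell, Mmp9, and 11 adjusted over the list alone; camera adjusted p 3e-05). Ngp, a neutrophil granule protein of this list, lay at 2330 ± 636 against 110 ± 73.9 CPM without passing (edgeR adjusted p 0.0909). B lineage genes were lower (1 of 16, and 3 adjusted over the list alone; camera adjusted p 0.000768), and Dntt, which diversifies antigen receptors, had 0 counts in the floxed libraries, at least 58.3-fold lower without passing. Control 2 held most of its counts, at 4.43 CPM against 0.339 and 0.611, and without it the bound was 16.4. Cell cycle genes were lower, with 0 of 32 passing by edgeR over all genes or over the list alone (4.68e-05), and so were interferon-stimulated genes, with 0 of 35 (0.0199), a call lost without control 2 (0.145) or floxed 2 (0.0814). Genes of the unfolded protein and amino acid stress response were lower (1 of 22, Chac1, and 1 higher and 6 lower adjusted over the list alone; 0.0429), a call lost without control 3 (0.188), floxed 1 (0.136) or floxed 3 (0.0589). With an estimated correlation the camera adjusted p was 0.980 for each of these 5 lists, so none held, and by fry the B lineage list alone passed (adjusted p 0.0396).

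In the MxCre set titled A2, edgeR called few genes between floxed and control libraries. Cish, which restrains cytokine signalling through STAT5, rose from 2.90 ± 1.38 to 20.4 ± 5.84 CPM, a log2 fold change of 2.81 ± 0.40 (SE; edgeR adjusted p 0.00808). Gabbr1, a GABA receptor subunit gene, rose from 0.582 ± 0.188 to 6.70 ± 0.921 CPM (edgeR adjusted p 0.00808). Neurl1b, a ubiquitin ligase of the Notch pathway, fell from 20.7 ± 1.61 to 3.77 ± 1.14 CPM (edgeR adjusted p 0.0142), and Slc12a4, a potassium chloride cotransporter gene, from 44.2 to 8.98 (0.0298). These 4 are all the genes called, 1489 genes having an unadjusted p under 0.05, and 196 genes were called by DESeq2 and 1202 by voom with sample weights. The libraries did not overlap for 2109 genes, or 15%, against a mean of 10% over the 10 splits, which a single split can exceed by chance. The number of genes was 0 without control 1, 0 without control 2, 1 without floxed 1, 18 without floxed 2 and 10 without floxed 3, and 0 with a term for Y-positive libraries, with which the log2 fold changes were 3.96 for Gabbr1, 2.84 for Cish, -2.78 for Neurl1b and -2.61 for Slc12a4. In a fit to the set's 6 libraries alone 0 of these 4 genes were called.

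In the MxCre set titled A2, most list calls were lost without 1 or another library, and those of T and NK genes and of B lineage genes were not. T and NK genes were higher (0 of 21 over all genes, 6 adjusted over the list alone; camera adjusted p 2.15e-06), with a median log2 fold change of 1.74 that was 1.11 without floxed 3 (0.0139). B lineage genes were higher too (0 of 16; 0.000322), with a median of 1.48 that was 2.85 without control 3. Erythroid genes were higher (0 of 17 over all genes, 17 adjusted over the list alone; 0.0188), with a median log2 fold change of 5.49 that turned to -1.28 without floxed 3. Interferon-stimulated genes were higher (0 of 35, and 9 adjusted over the list alone; 0.0379), with a median of 1.06 that turned to -0.14 without floxed 3, and the call was also lost without control 1 (0.131) or control 3 (0.0560). Monocyte and macrophage genes were lower (0.00252), a call lost without control 1 (0.0934) or floxed 1 (0.163). Also lower were p53 targets (0.00252; 0.0542 without control 1), immediate-early genes (0.00507; 0.0878 without control 1), glycolysis and hypoxia genes (0.00507; 0.263 without floxed 3) and adhesion and homing genes (0.0270; 0.281 without control 1, 0.313 without floxed 1, 0.0529 without floxed 2). In these lists 0 genes passed by edgeR over all genes, and 1 glycolysis gene adjusted over the list alone. Stromal and endothelial genes were higher (0 of 13; 0.0270; 0.0878 without control 1, 0.316 without floxed 2), and the erythroid call was 0.0646 without control 2. With an estimated correlation none of these 10 lists held, the camera adjusted p being 0.635 or 0.845, and none passed by fry.

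In the MxCre set titled A1b, Gla, the lysosomal alpha-galactosidase gene on the X chromosome, was the only gene called by edgeR. It rose from 21.8 ± 2.26 to 44.2 ± 6.43 CPM, a log2 fold change of 1.02 ± 0.15 (SE; edgeR adjusted p 0.0312), and lay higher in 3 of 3 floxed libraries than in any control. Pbx3, a cofactor of HOXA9, lay at 133 ± 25.2 against 11 ± 2.93 CPM and Sparc, a matrix protein gene, at 5.21 against 1.55, both without passing (edgeR adjusted p 0.0667 and 0.0664). At an unadjusted p under 0.05 there were 2450 genes, and 478 genes were called by DESeq2 and 12 by voom with sample weights. The libraries did not overlap for 1987 genes, or 14.1%, against a mean of 10% over the 10 splits, which a single split can exceed by chance. The number of genes was 1535 without floxed 1, 11 without control 2, and 0 without control 1, without control 3 or without floxed 3. Gla was not called with a correction for gene length, with no filter on low counts or in a fit to the set's 6 libraries alone, while its log2 fold change stayed at 0.89 to 1.10 over all alternatives, so these lost calls do not show that length or filtering accounts for the change.

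List tests in the MxCre set titled A1b gave genes of respiration and of acute signalling as higher. Nuclear oxidative phosphorylation genes were higher (0 of 29 over all genes, 5 adjusted over the list alone; camera adjusted p 2.38e-08), with a median log2 fold change of 0.41 that was 0.13 without floxed 2 (0.0200), the library whose longer genes were lower. Immediate-early genes were higher (0 of 18, and 16 adjusted over the list alone; 1.66e-07), among them Ier3, at 2.93 against 15.3 CPM, and their median of 2.23 was 0.67 without floxed 3 (0.0166). Stromal and endothelial genes were lower (0 of 13, and 8 adjusted over the list alone; 3.39e-06). Granulocytic genes were higher (0 of 27; 1.76e-05), with a median of 1.12 that was 0.55 without floxed 2 (0.0130), and glycolysis and hypoxia genes were higher (0 of 25, and 3 adjusted over the list alone; 0.00322), lost without floxed 1 (0.141). MLL-fusion targets were lower (0 of 20, and 1 adjusted over the list alone; 0.00943), lost without control 3 (0.0611) or floxed 2 (0.179). MYC and ribosome biogenesis genes were higher (0 of 26, and 1 adjusted over the list alone; 0.0128), with a median log2 fold change of 0.21 that turned to -0.20 without floxed 1 and was lost without control 3 (0.381). Interferon-stimulated genes were lower (0 of 35; 0.0241), lost without control 2 (0.0552), floxed 1 (0.0656) or floxed 3 (0.443). With an estimated correlation none of the 8 lists held, the smallest camera adjusted p being 0.122 for the stromal and endothelial genes, which alone passed by fry (adjusted p 0.00414).

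Lists of the SWI/SNF complexes themselves did not pass in any set: over the 4 sets the smallest camera adjusted p was 0.642 for core subunits, 0.245 for BAF-specific subunits and 0.519 for PBAF and ncBAF subunits. Nor did stem and progenitor genes (0.173), although Cebpa rose and Kit fell in the VavCre Arid1b set, megakaryocyte genes (0.473), genes of mast cells, basophils and eosinophils (0.354), heat shock genes (0.493) or apoptosis regulators (0.0793). The sex-linked list joins Xist with Y-linked genes, which differ between the sexes in opposite directions, so a test for a shared direction is not used for it. In the VavCre Arid1b set 2 of its 6 genes rose and 4 fell adjusted over the list alone, and 0 passed over all genes.

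The VavCre sets shared part of their changes. Both had lower Cd63, a tetraspanin of granule membranes, lower Ets1, a lymphoid transcription factor, and lower Ndrg2, Bai1, Aldh1l1 and Oas1g. Their called genes overlapped in 36 that fell in both, against 4.57 expected (Fisher's exact test, two-sided p 1.61e-22), and in 7 that rose in both, against 1.23 (p 0.000183), though genes are not independent replicates. Of the 926 genes of the VavCre Arid1b set, 83.3% moved in the same direction in the VavCre Arid2 set, 21.8% in the MxCre set titled A2 and 60.3% in the MxCre set titled A1b. In the MxCre set titled A2 sex follows genotype in the opposite way to the VavCre Arid1b set. Opposite changes in that pair therefore cannot be told apart from sex. Across genes, log2 fold changes of the VavCre sets had a Pearson correlation of 0.47 and a Spearman correlation of 0.48, and without control 3 of the VavCre Arid1b set the former was 0.23. Evpl, a cell envelope gene, was called in both in opposite directions, at 2.32 and -5.18 on the log2 scale. Slc12a4 was called in opposite directions in the VavCre Arid1b set, where it rose, and the MxCre set titled A2, where it fell.

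Between the other pairs of sets the correlation across genes was weaker or negative. It was -0.29 (Spearman -0.18) between the MxCre sets, and -0.02 without control 2 of the set titled A1b. It was -0.33 (-0.38) between the VavCre Arid1b set and the MxCre set titled A2, and -0.17 without control 3 of the former or floxed 2 of the latter. Sex follows genotype in opposite ways in that pair, so opposite effects of sex and of deletion cannot be told apart there. Between the VavCre Arid1b set and the MxCre set titled A1b it was 0.27 (0.11), and 0.03 without control 2 of the MxCre set or 0.14 without its floxed 2. It was -0.12 (-0.19) between the VavCre Arid2 set and the MxCre set titled A2, and 0.01 without floxed 2 of the latter. Between the VavCre Arid2 set and the MxCre set titled A1b the 2 measures differed in sign, at 0.06 and -0.10, and the first was -0.28 without control 2 of the MxCre set, -0.01 without control 2 of the VavCre set and -0.001 without floxed 3 of the MxCre set.

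Between control libraries with the same Cre, edgeR called 6 genes with VavCre and 0 with MxCre, and those named were chosen after their values were seen. Isg20l2, a nucleolar exonuclease gene, and Rrnad1 were lower in the controls of the VavCre Arid2 set than in those of the VavCre Arid1b set, at 66.2 ± 3.28 against 109 ± 7.10 and 56.1 ± 4.34 against 118 ± 9.85 CPM (edgeR adjusted p 0.0101 and 0.0119). C530005A16Rik and the microRNA entries Mir8094, Mir3064 and Mir6418, whose reads overlap other genes, were also lower, by 0.75 to 1.09 on the log2 scale. These 6 were all the genes called, with 1762 at an unadjusted p under 0.05, and DESeq2 called 335 and voom with sample weights 2946. The controls of the VavCre Arid1b set are all Y-positive and those of the VavCre Arid2 set all Y-negative, so sex and set are confounded here. With a term for Y-positive libraries edgeR called 0. All 6 kept their direction, their median size went from 1.01 to 1.04 and their median SE from 0.159 to 0.215. The lost calls thus do not show that sex is the reason. The term is estimated only in groups that hold both sexes, which these controls do not, so kept directions do not exclude sex. Without the 3 libraries that stood apart 461 genes were called. Their number was 3 without control 1 or control 2 of the VavCre Arid1b set, 56 without its control 3, and 0 without control 1 or control 2 of the VavCre Arid2 set. Between the MxCre controls 0 genes were called by edgeR, with 817 at an unadjusted p under 0.05, 28 called by DESeq2 and 36 by voom with sample weights, and 5 were called without control 2 of the set titled A1b.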

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

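The tests of gene length and of a term for Y-positive libraries were chosen only after the results were seen. The test of sex was set before its own result, but it used the sex of the libraries as seen in the data. Those of differences within groups and of other splits were chosen before their results were seen.

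These results stood out because the change from control to floxed libraries differed between a pair of sets, by edgeR's test of the difference. Between the VavCre sets 2 genes differed. Evpl, a cell envelope gene, rose by 2.32 on the log2 scale in the VavCre Arid1b set and was at -5.18 in the VavCre Arid2 set, a difference of -7.51 (edgeR adjusted p 0.000216), and 5031425F14Rik differed by -4.82 (0.00252). The number of genes was 12 without control 3 and 13 without floxed 1 of the VavCre Arid1b set, and 4 without control 3 or without floxed 2 of the VavCre Arid2 set. The 40 splits were the real one and random draws that relabelled the libraries within all 4 sets at once, which share 1 estimate of the spread. Of these, 2 gave at least as many genes, the real one included, and the highest other split gave 11, so chance is not excluded. A draw may keep the real grouping in 1 set of a pair, so high counts do not show a structure beyond the groups.

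Between the MxCre sets 27 genes differed, 10 higher and 17 lower in the set titled A1b. They include Gla (1.53 on the log2 scale, edgeR adjusted p 0.0130), Gabbr1 (-4.61, 0.0136), the kinase gene Prkca (-6.10, 0.0216), the collagen gene Col6a3 (-9.47, 0.0265) and Reps2 (-4.64, 0.0290). Leaving out libraries of the set titled A2 gave 2 genes (control 1), 13 (control 2), 7 (control 3), 10 (floxed 1) and 17 (floxed 2). Leaving out those of the set titled A1b gave 7 (control 1), 5 (control 3), 1419 (floxed 1), 1 (floxed 2) and 2 (floxed 3). Of 40 splits, 3 gave at least as many genes, the real one included. The highest other split gave 887, several times the real count, so chance is not excluded.

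The VavCre Arid1b set and the MxCre set titled A2 differed in 1036 genes, 464 higher and 572 lower in the latter. The phosphatase gene Dusp3 (-4.20, edgeR adjusted p 0.00137), Ints4 (-1.37, 0.00274) and Limd1 (-2.51, 0.00274) lay lower in the MxCre set's change, and Cd63, a granule membrane tetraspanin (3.57, 0.00137), and the autophagy gene Atg12 (1.60, 0.00274) higher. Of 40 splits only the real one gave as many genes, the highest other giving 286. As the smallest share 40 splits can give, with several pairs tested, this does not exclude chance. Sex runs opposite to genotype in these sets. With a term for Y-positive libraries 13 genes were called, 10 of them among the 1036, and 1032 of the 1036 kept their direction. Their median size went from 2.69 to 2.13 and their median SE from 0.658 to 1.05. The lost calls come mostly with the wider error and do not show that sex is the reason. Kept directions do not exclude sex either, as the term is estimated only in groups of other sets that hold both sexes. The count was 452 without control 1, 546 without control 3, 298 without floxed 3 and 532 without floxed 4 of the VavCre set, and 316 without control 1, 673 without control 2, 400 without floxed 1, 479 without floxed 2 and 2076 without floxed 3 of the MxCre set. The VavCre Arid1b set and the MxCre set titled A1b differed in 105 genes, 45 higher and 60 lower in the latter. They include Ppp2cb, a phosphatase subunit (1.48), Cd63 (2.91), Nos1ap (-3.54), Ikzf1, a lymphoid transcription factor (-1.30), and Rnf7 (1.74), each with an edgeR adjusted p of 0.0141. Of 40 splits only the real one gave as many, the highest other giving 1. That is again the smallest share 40 splits can give, over several pairs tested, and does not exclude chance. The count was 11 without control 1, 38 without control 3, 223 without floxed 1, 0 without floxed 3 and 31 without floxed 4 of the VavCre set, and 1 without control 1, 244 without control 2, 14 without control 3, 177 without floxed 1, 234 without floxed 2 and 161 without floxed 3 of the MxCre set.

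The VavCre Arid2 set and the MxCre set titled A2 differed in 69 genes, 58 higher and 11 lower in the latter. Ets1, a lymphoid transcription factor (5.39, edgeR adjusted p 0.0183), Mlph (10.2, 0.0220), the hyaluronidase gene Tmem2 (3.10, 0.0220), Gabbr1 (4.14, 0.0220) and Paqr8 (9.56, 0.0220) lay higher. The Mlph and Paqr8 values rest on few counts in the floxed libraries of the VavCre Arid2 set. The count was 3 without control 1, 0 without control 2, 161 without control 3, 0 without floxed 1 and 2 without floxed 2 of the VavCre set, and 3 without control 1, 0 without control 2, 9 without control 3, 17 without floxed 1, 25 without floxed 2 and 666 without floxed 3 of the MxCre set. Of 40 splits, 2 gave at least as many genes, the real one included, and the highest other gave 337, so chance is not excluded. The VavCre Arid2 set and the MxCre set titled A1b differed in 212 genes, 127 higher and 85 lower in the latter, among them Evpl (7.28, 0.000325), Nudt4 (1.77, 0.000325), 5031425F14Rik (5.45, 0.000325), the circadian repressor gene Bhlhe40 (3.19, 0.00575) and the phosphatase gene Acp5 (3.50, 0.00599). The count was 20 without control 1, 40 without control 2, 48 without control 3, 16 without floxed 1 and 15 without floxed 2 of the VavCre set, and 7 without control 1, 734 without control 2, 5 without control 3, 1058 without floxed 1 and 414 without floxed 3 of the MxCre set. With a term for Y-positive libraries 7 genes were called, while all 212 kept their direction. Their median size went from 2.28 to 2.19 and their median SE from 0.501 to 0.545. The lost calls do not show that sex is the reason, and the kept directions do not exclude it. Of 40 splits, 2 gave at least as many genes, the real one included, and the highest other gave 483, so chance is again not excluded.

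For the counts within sets, 10 splits of 6 libraries are too few for a share under 0.05. In each set 1 split of 10, the real one, gave as many genes: 926 against at most 1 in another split for the VavCre Arid1b set, 185 against 0 for the VavCre Arid2 set, 4 against 0 for the MxCre set titled A2 and 1 against 0 for that titled A1b. For the controls it was 1 split of 10 with VavCre (6 genes against 0), and 10 of 10 with MxCre, where the real split called 0 by edgeR, with 817 at an unadjusted p under 0.05, 28 by DESeq2 and 36 by voom with sample weights.

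Both VavCre sets changed many genes, 926 and 185, and the deleted gene may be the reason, as may other differences between the leukaemias. The Y-positive difference within groups of the other sets was scaled by the set's own difference in the share of Y-positive libraries. Its slope on the change of the called genes would be 1 if sex alone acted, without noise. The genes were chosen by that same change, so noise would pull the slope under 1. The slopes were 0.049 ± 0.241 (jackknife SE over libraries, 898 genes) and 0.015 ± 0.089 (180 genes). They rest on 9 and 6 libraries in groups that hold both sexes. In the MxCre set titled A1b, the only library of its sex in each group lay apart along the first principal component. These were Y-negative control 2, at -70.8, and Y-positive floxed 1, at -61. Their shifts may cancel, so a slope near 0 does not exclude sex. With a sex term all 926 genes kept their direction. The call ended for most as the median SE went from 0.43 to 0.561 while the median size went from 1.86 to 1.71. That term rests on the same groups of other sets that hold both sexes, so the kept directions do not exclude sex either. After a correction for gene length 883 of 926 and 173 of 185 genes were still called, which argues against a length trend as the whole cause. The first axis of differences within groups of the other 18 libraries held 0.592 ± 0.176 and 0.444 ± 0.131 of the summed squared change of the called genes, so deletion and differences between leukaemias of the same genotype cannot be told apart with 3 libraries each. Leaving out control 1, control 3, floxed 3 or floxed 4 gave 65, 403, 62 and 305 genes in the VavCre Arid1b set, and leaving out control 1, control 2, floxed 1 or floxed 2 gave 61, 27, 15 and 16 in the VavCre Arid2 set.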

How the results depend on the processing

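A term for Y-positive libraries, a fit without 3 libraries that stood apart, the gene length correction and the tests without genes of chromosomes X and Y or 12 were chosen only after the data were seen. Counts are given in the order VavCre Arid1b set, VavCre Arid2 set, MxCre set titled A2, MxCre set titled A1b. DESeq2 size factors within edgeR (12 counts), estimation without the robust option (4) and a 2-fold limit (4) left every count within 1.5 times. None of the 49, 22, 4 and 1 genes named by rule and called in a set changed direction under any alternative. These genes were chosen as called, and the leading ones as separated, so their kept directions were largely set by that choice. For the moved values below the cause was not tested, except that fits with fewer libraries have less data. With the term for Y-positive libraries the median SE of the 926 genes of the VavCre Arid1b set rose from 0.43 to 0.561. Their median size went from 1.86 to 1.71 and all kept their direction. This does not exclude sex, as the term is estimated only in groups of other sets that hold both sexes.

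The tool moved most counts. DESeq2 called 1815, 1095, 196 and 478 genes, and voom with sample weights 4189, 4679, 1202 and 12. For differences between sets DESeq2 called 252 (VavCre sets), 604 (MxCre sets), 1909 (VavCre Arid1b and MxCre titled A2), 770 (VavCre Arid1b and MxCre titled A1b), 714 (VavCre Arid2 and MxCre titled A2) and 1146 (VavCre Arid2 and MxCre titled A1b), and voom, in that order and leaving out the MxCre pair, which did not move, 2484, 4698, 768, 4769 and 1725. Between controls DESeq2 called 335 (VavCre) and 28 (MxCre), and voom 2946 and 36.

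With no filter on low counts the VavCre Arid2 count was 103 and the count of the MxCre set titled A1b was 0, where DESeq2 called 478, voom 12 and 2450 genes had an unadjusted p under 0.05. The differences became 14 (MxCre sets), 64 (VavCre Arid1b and MxCre titled A1b), 18 (VavCre Arid2 and MxCre titled A2) and 63 (VavCre Arid2 and MxCre titled A1b). With 1 CPM in 3 libraries the MxCre set titled A2 had 7 genes and the MxCre pair 44. With only the 6 libraries of a set, the VavCre Arid2 set had 1030 and the MxCre set titled A1b 0 by edgeR. With the gene length correction the latter had 0 and the VavCre pair 4. Without genes on X and Y the MxCre sets had 7 and 0, and without chromosome 12 the set titled A2 had 7.

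With the replicate number as a block, edgeR called 1, 3, 1 and 1 genes in the sets, 1 for the MxCre pair, 1 for VavCre Arid1b and MxCre titled A2, 0 for VavCre Arid1b and MxCre titled A1b, 0 for VavCre Arid2 and MxCre titled A2, 10 for VavCre Arid2 and MxCre titled A1b, and 0 for the VavCre controls. Libraries of the same number did not resemble each other more: the correlations of their deviations from group means ran from -0.38 to 0.36, so the numbers do not pair the libraries, and the block uses up residual degrees of freedom.

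With a term for Y-positive libraries the sets had 101, 104, 0 and 2 genes, the VavCre pair 4, VavCre Arid1b and MxCre titled A2 13, VavCre Arid2 and MxCre titled A2 255, VavCre Arid2 and MxCre titled A1b 7, and the VavCre controls 0. For the last 2 all genes kept their direction. The median size of the 212 genes went from 2.28 to 2.19 and their median SE from 0.501 to 0.545. For the 6 genes these went from 1.01 to 1.04 and from 0.159 to 0.215. These lost calls do not show that sex is the reason, and the kept directions do not exclude it. Without the 3 libraries that stood apart (control 3 of the VavCre Arid1b set, floxed 3 of the MxCre set titled A2 and floxed 2 of that titled A1b) the VavCre Arid2 set had 1144 genes, all 185 among them, and the MxCre sets 33 and 8. The differences were then 144 (VavCre sets), 4 (MxCre sets), 1849, 322, 1991 and 738 in the order above, and the VavCre controls 461.

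Leaving out 1 library at a time gave 62 to 734 genes in the VavCre Arid1b set, 15 to 227 in the VavCre Arid2 set, 0 to 18 in the MxCre set titled A2 and 0 to 1535 in that titled A1b. The differences ranged from 2 to 13 (VavCre sets), 1 to 1419 (MxCre sets), 298 to 2076 (VavCre Arid1b and MxCre titled A2), 0 to 244 (VavCre Arid1b and MxCre titled A1b), 0 to 666 (VavCre Arid2 and MxCre titled A2) and 5 to 1058 (VavCre Arid2 and MxCre titled A1b), and the controls from 0 to 56 (VavCre) and 0 to 5 (MxCre). Groups then left with 2 libraries share the spread of all groups.

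Correlations of fold changes across genes ranged, without 1 library, from 0.231 to 0.503 (VavCre sets), -0.326 to -0.023 (MxCre sets), -0.484 to -0.167 (VavCre Arid1b and MxCre titled A2), 0.031 to 0.421 (VavCre Arid1b and MxCre titled A1b), -0.267 to 0.009 (VavCre Arid2 and MxCre titled A2, reversed without floxed 2 of the MxCre set) and -0.279 to 0.202 (VavCre Arid2 and MxCre titled A1b, reversed to -0.279 without MxCre control 2, -0.012 without VavCre control 2 and -0.001 without MxCre floxed 3). Over genes with a mean log2 CPM above 3 they were -0.199, -0.532, 0.130, -0.221 and, reversed, -0.179 for the pairs after the first.

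The 31 list calls all ended with an estimated correlation, and 2 passed by fry. Without 1 library the erythroid and interferon-stimulated medians in the MxCre set titled A2 ranged up to 5.91 and 1.57, and that of MYC and ribosome biogenesis genes in the set titled A1b up to 0.475. Under these omissions 157 list results stayed called, 26 did not, and 3 changed direction, to medians of -1.28 (erythroid) and -0.14 (interferon-stimulated) without floxed 3 of the MxCre set titled A2 and -0.20 (MYC and ribosome biogenesis) without floxed 1 of that titled A1b. Without the 3 libraries that stood apart the first of these lists was at -1.82 and the next at -0.139.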

Other observations

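The tests of the Y-linked genes and the genes named in the next paragraph were chosen only after the values were seen. Those of chromosome 12 were set before their own results, but for libraries picked after that chromosome was seen to lie higher in them.

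Some blood cell genes were nearly off in single libraries of several groups. Ikzf2, which encodes the transcription factor Helios, was at 1.80 to 3.72 CPM in the floxed libraries of the VavCre Arid1b set, and also at 0.549 in floxed 3 of the VavCre Arid2 set, 1.66 in floxed 1 of the MxCre set titled A2 and 1.11 in control 2 of that titled A1b, while the remaining 18 libraries lay at 73.9 to 376. Cpa3, a mast cell protease, ranged from 0.0649 to 460 CPM, and Flt3, a progenitor receptor, from 1.43 to 1070. Low Ikzf2 thus occurred in a control library too.

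Genes on chromosome 12 lay higher in control 3 of the VavCre Arid1b set and, less so, in control 2 of the MxCre set titled A1b, by medians of 0.507 and 0.232 on the log2 scale over 381 genes. Genes of other chromosomes matched on length and level had a median of 0.024 ± 0.028 (1030 genes) in the former, which argues against a trend with length or level. An extra copy in all cells would give 0.585; in control 3 of the VavCre Arid1b set the lowest of 4 stretches of the chromosome with like numbers of genes was at 0.437 ± 0.091 (SE), so a gain of the whole chromosome is a candidate explanation. In control 2 of the MxCre set titled A1b the lowest stretch was at 0.190 ± 0.079, and a gain in part of the cells and other differences cannot be told apart at that size. No biological explanation from the design was tested, and DNA was not measured.

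Y-linked genes lacked reads in 3 Y-positive MxCre floxed libraries: Eif2s3y (0 counts) and Ddx3y (2) in floxed 1 and Eif2s3y (1) in floxed 3 of the set titled A2, and Uty and Ddx3y (0 each) in floxed 1 of that titled A1b. The 7 other Y-positive libraries had Eif2s3y at 89.9 to 126, Uty at 28.9 to 40.2 and Ddx3y at 94.0 to 159 CPM, and the loss was seen in 3 of 4 MxCre floxed and 0 of 6 other Y-positive libraries, a grouping noticed in these values, for which reason a test of it is not used, and libraries of a group may share a donor or primary leukaemia. Uty, which lies between Eif2s3y and Ddx3y on GRCm38, had 545 counts in floxed 1 of the MxCre set titled A2, so a single unbroken deletion does not give these values there. Kdm5d was at no less than 64.0% of its mean in the other Y-positive libraries (spread 4.62%), so few Y-positive cells do not give them. Separate losses of these genes in the MxCre floxed leukaemias, or in the animals they came from, may explain them, which was not tested.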
